A study of Homo sapiens with 4 samples.

How the data were processed

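RNA was measured in 4 sequencing libraries of HEK293T cells, a widely used line derived from human embryonic kidney cells. Per the labels' protocols the cells stably expressed a V5-tagged PRADA construct directed to the mitochondrial matrix, a construct for labelling molecules in its surroundings. They were given 100 µM of the uridine analogue 4-thiouridine (s4U) for 5 h and then 0.5 mM alkyne phenol, with s4U kept in the medium, for 30 min. In the labelled group the reaction was started by adding 10 mM D-amino acid for 30 min, and in the unlabelled group the D-amino acid was left out. The series design text describes the material as labelled and enriched, and the labels give ribosomal RNA depletion before library preparation. Groups and replicate numbers were taken from the sample titles, with 2 libraries per group. Xenograft material named in the design text was not analysed here.

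The deposited table holds whole-number fragment counts per gene, not normalized, for 62700 genes. Per the file headers the authors made these counts with featureCounts 1.6.4 on the GENCODE 44 annotation, counting read pairs with both ends mapped and leaving out chimeric pairs, over exons summed by gene, with no strand option and no option for multi-mapping reads. Per the submitters' processing notes the reads were aligned with STAR 2.7.9a to GRCh38, and DESeq2 1.42.0 was also used. Removal of duplicate reads is not given in the sources used here. A second deposited table gives the counts of alignment records by assignment status, and the total assigned in it equals the sum of the gene counts in each library. Multi-mapped records in that table are alignments, so 1 fragment can be listed several times.

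This counting affects the measurements in 3 ways. Without strand, MT-ND6 and the other mitochondrial genes annotated on the minus strand cannot be told apart from antisense RNA of the opposite strand. Mitochondrial genes adjoin or overlap each other, and fragments that touch 2 genes are ambiguous and stay unassigned, which mostly affects short genes such as MT-ATP8 and the tRNAs. Nuclear genes whose exons overlap an annotated gene on either strand lose fragments in the same way. Fragments that map equally well to the mitochondrial chromosome and to a nuclear pseudogene copy are left out, while those with a difference go to 1 of the copies, so counts of these pseudogenes are uncertain.

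All 62700 gene identifiers were paired with symbols. Biotypes came from GENCODE 29 and covered 58207 of the genes. Coordinates are those of the deposited table, on GRCh38 and counted from 1. All sample columns of the table were used.

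Counts were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, quasi-likelihood) in R 4.3.3 after filterByExpr and TMM normalization, with Benjamini-Hochberg adjustment over 18973 genes and a threshold of 0.05 on the adjusted p. Standard errors are the log2 fold change divided by the square root of the F statistic. The 4 libraries entered 1 fit with no block. Counts per 1000000 (CPM) are scaled by TMM, and log2 CPM for gene list tests used a prior count of 2. Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over 22 lists, with an estimated correlation and with fry as alternatives. Shares of counts were compared with a two-sided exact permutation test written in Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3. For 2 against 2 libraries that test has 6 arrangements, so its smallest possible p is 0.333. Intervals for shares are 95% Wilson intervals from SciPy 1.17.1. They cover counting error only, because reads without molecular identifiers are not independent molecules. Plots were drawn with matplotlib 3.10.9.

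The 22 gene lists and the rule for named genes were fixed before the data were examined. The rule named all 13 mitochondrial mRNAs, both mitochondrial rRNAs and the 3 mitochondrial tRNAs with the highest mean CPM. It also named the 10 nuclear genes with the largest rise and the 10 with the largest fall (all, if fewer) among those with an adjusted p under 0.05, a mean CPM of at least 5 and groups that did not overlap. Pseudogene copies of mitochondrial genes were excluded there, and genes with a biotype had to be protein coding or long non-coding. Finally, the rule named the 3 tested members with the smallest p in each list. The values of 2 genes that the rule named are not reported here. The lists covered mitochondrial mRNAs, rRNAs, tRNAs and their nuclear pseudogene copies, nuclear-encoded respiratory chain subunits, mitochondrial ribosomal proteins, matrix enzymes and mitochondrial gene expression factors, cytosolic ribosomal proteins, nuclear long non-coding RNAs, small non-coding RNAs, small nucleolar RNAs, histones, endoplasmic reticulum chaperones, oxidative stress, integrated stress, heat shock, immediate early and p53 target genes, cytosolic housekeeping mRNAs, and markers of blood cells and of fibroblasts and endothelium.

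The test was tried on simulated data for the comparison of labelled with unlabelled libraries, over 18438 genes drawn from the real means and library sizes. It recovered 76 of 100 genes changed 2-fold and 95 of 100 changed 4-fold, with 3 false calls among 174. The changed genes were picked at random, rose and fell equally often, and no simulated library stood apart from the others. These rates therefore need not hold for a one-sided rise of abundant transcripts. MT-CO1, for example, had an edgeR adjusted p of 0.150 at a 4.53-fold change in the real libraries. The common biological coefficient of variation of the real libraries was 10.8%. Replicates within a group differed by more than sampling noise, with a chi-square per degree of freedom of 11.6 in the unlabelled and 8.20 in the labelled group, so no library was taken for a second deposit of another.

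Alternatives were DESeq2 size factors in edgeR, library size alone, library sizes and TMM from nuclear genes only, no filter, a filter of CPM of at least 1 in at least 2 libraries, the replicate number as a block, each library left out in turn, all libraries thinned to the lowest total, rRNA genes left out, DESeq2 1.42.0, stricter thresholds, and other denominators for the mitochondrial share. A fit with the trend over GC content and gene length removed was added after seeing the data. GC content was known for 96.0% of the genes tested.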

Results

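RNA was sequenced from HEK293T cells, a line derived from human embryonic kidney cells, that carried a PRADA construct targeted to the mitochondrial matrix. All cells received 100 µM s4U, a uridine analogue that is built into RNA during transcription, and 0.5 mM alkyne phenol. The labelled group of 2 libraries also received 10 mM D-amino acid for 30 min to start labelling, and the unlabelled group of 2 libraries did not. The titles call the libraries biological replicates and do not say how the cultures were separated, so p-values measure the spread between these libraries. The unlabelled libraries held 8172347 and 5771795 assigned fragments, and the labelled libraries held 9380258 and 12287451. A count of 3 fragments corresponded to 0.367, 0.520, 0.320 and 0.244 CPM of assigned fragments in these libraries, in that order. Values below are given for labelled against unlabelled libraries, the only contrast in the labels.

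The first question was how much of the captured RNA came from the mitochondrial chromosome, whose transcripts are made inside the matrix where the construct resides. Mitochondrial transcripts made up 9.04% of assigned fragments in unlabelled replicate 1 (95% Wilson interval 9.02 to 9.06%) and 10.4% in unlabelled replicate 2. They made up 27.0% in labelled replicate 1 and 30.9% in labelled replicate 2 (30.9 to 30.9%). The group means were 9.73% ± 0.980 (SD, n = 2) and 28.95% ± 2.77 (SD, n = 2), a 2.97-fold difference of 19.2 percentage points that was many times the spread within either group. The groups did not overlap, and the exact permutation test gave p = 0.333, two-sided, the smallest p that 2 against 2 libraries allow.

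**Figure D1:**
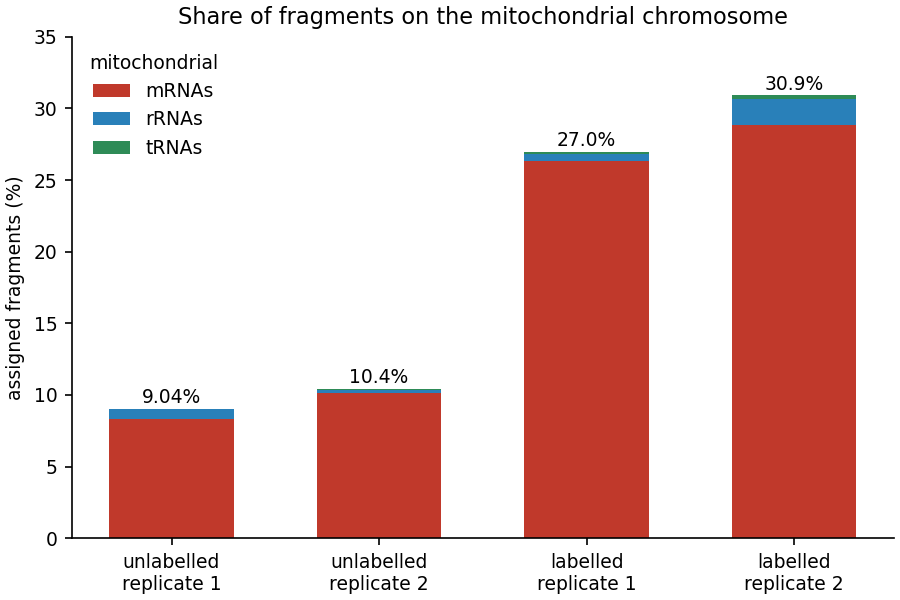
Bars show the share of assigned fragments (%) on the mitochondrial chromosome in each of the 4 libraries, split into mRNAs, rRNAs and tRNAs. The unlabelled libraries stand at 9.04% and 10.4% and the labelled ones at 27.0% and 30.9%.

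Most of this share was mRNA. The 13 mitochondrial mRNAs, which encode subunits of the respiratory chain and the ATP synthase, took 9.20% ± 1.27 (SD, n = 2) of unlabelled and 27.6% ± 1.77 (SD, n = 2) of labelled fragments. MT-CO1, a core subunit of cytochrome c oxidase, alone took 1.86% ± 0.180 and 6.58% ± 0.223. The 22 mitochondrial tRNA genes took 0.0679% ± 0.0323 and 0.219% ± 0.0544. The mitochondrial rRNAs overlapped between the groups, at 0.691% and 0.231% in the unlabelled and 0.463% and 1.81% in the labelled libraries. Signal recognition particle RNA (RN7SL genes) went the other way, at 1.61% and 2.84% against 1.02% and 1.06%. Part of that fall follows from the larger mitochondrial share, because these are shares of all fragments, and unlabelled replicate 2 held the highest value.

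Gene by gene, transcripts of the mitochondrial chromosome, nuclear copies of its genes and other nuclear genes were higher in labelled libraries. Of 18973 genes tested with edgeR, 51 were higher and 3 lower in labelled libraries at an adjusted p under 0.05. The 51 comprised 23 of the 35 mitochondrial genes tested, 14 of 43 nuclear pseudogene copies of mitochondrial genes, and 14 other nuclear genes. By fold change, mitochondrial genes ranked above the nuclear genes outside the pseudogenes with an area under the ROC curve of 0.997. At an unadjusted p under 0.05 there were 2191 genes, and the groups did not overlap for 44.6% of the genes tested, against 33.3% by chance. The count of calls depended on single libraries, with 3985 genes without unlabelled replicate 1, 937 without unlabelled replicate 2 and 93 without labelled replicate 1. Unlabelled replicate 2 stood apart, with a median absolute log2 difference over genes of 0.257 to unlabelled replicate 1, which differed from the labelled libraries by 0.184 and 0.202. With scaling by library size alone the split was 69 higher and 2675 lower, because that scaling moved the median log2 fold change of all genes to -0.37.

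**Figure D2:**
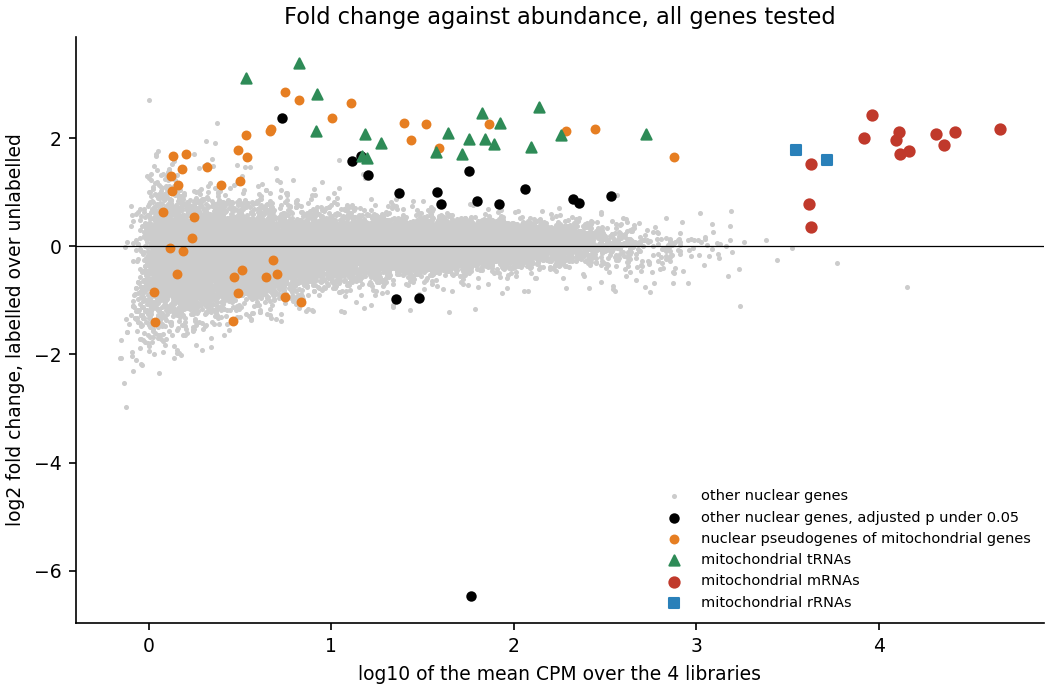
Each point is a gene, with the log10 of its mean CPM over the 4 libraries on the horizontal axis and its log2 fold change, labelled over unlabelled, on the vertical axis. Mitochondrial genes lie above 0 throughout, from 0.36 to 3.38. Other nuclear genes centre on -0.01, a level that the TMM scaling sets near 0.

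All 13 mitochondrial mRNAs had a positive log2 fold change, with a median of 1.96. The edgeR adjusted p passed the threshold for 4 of them over all genes tested and for 12 of 13 adjusted over the list alone, and DESeq2 passed 11 of them over all genes. MT-ND1 (ENSG00000198888, chromosome M, 3307 to 4262), a subunit of complex I, had the largest log2 fold change of the 13, at 2.42 ± 0.34 (SE), with an adjusted p of 0.00725 and 2885 CPM ± 321 (SD, n = 2) in unlabelled against 15457 CPM ± 2333 (SD, n = 2) in labelled libraries. MT-CYB, the cytochrome b of complex III (14747 to 15887), rose by a log2 fold change of 2.11 ± 0.36 (adjusted p 0.0289), and MT-CO3 of cytochrome c oxidase (9207 to 9990) by 1.96 ± 0.35 (adjusted p 0.0414). MT-ND6, a complex I subunit on the minus strand (14149 to 14673), rose by 2.01 ± 0.33 (adjusted p 0.0248), with the limit that unstranded counts include any RNA antisense to it. MT-CO1 (5904 to 7445), the most abundant of the 13, went from 16567 CPM ± 1088 to 74988 CPM ± 6639, a log2 fold change of 2.18 ± 0.51 with an adjusted p of 0.150.

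The other mRNAs that missed the threshold over all genes were MT-CO2 at 2.08, MT-ND4 at 2.12, MT-ND5 at 1.88, MT-ATP6 at 1.76, MT-ND2 at 1.70 and MT-ND4L at 1.53, with adjusted p-values between 0.0845 and 0.141. Complex I subunit MT-ND3 (10059 to 10404) had a log2 fold change of 0.78 ± 0.31 (edgeR adjusted p 0.381). MT-ATP8 (8366 to 8572), a small ATP synthase subunit whose gene overlaps MT-ATP6, had 0.36 ± 0.33 (adjusted p 0.697), the only one of the 13 not past the threshold over the list alone. Its labelled libraries stood at 4157 and 5399 CPM and its unlabelled libraries at 2529 and 4923 CPM. Without unlabelled replicate 2 its log2 fold change was 0.92, and without unlabelled replicate 1 it was -0.01. For MT-ND3 these values were 1.24 and 0.47. With library size alone MT-ATP8 stood at -0.01.

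**Figure D3:**
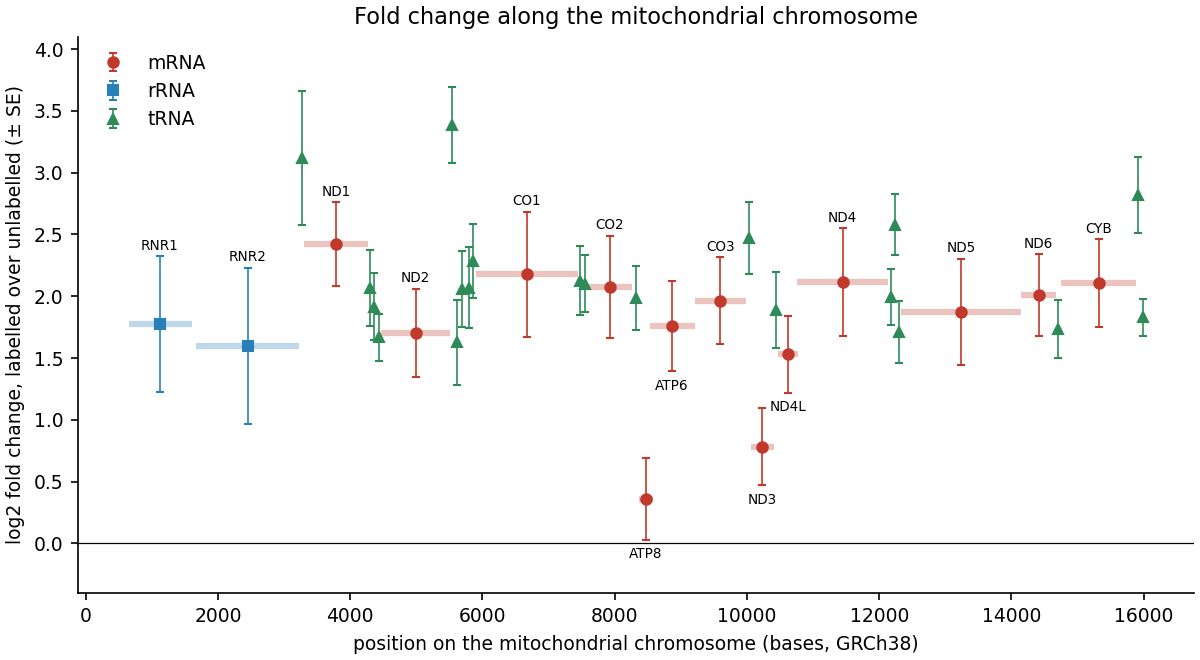
Log2 fold change, labelled over unlabelled, with its SE, for each mitochondrial gene tested, placed at its midpoint in bases on the mitochondrial chromosome (GRCh38), with pale bars for the extent of mRNA and rRNA genes. Most genes lie near 2, and MT-ATP8 at 0.36 and MT-ND3 at 0.78 lie lowest.

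Mitochondrial tRNAs rose as a group, with 19 of the 20 tested past the edgeR threshold over all genes, 13 past DESeq2, 20 adjusted over the list alone, and a median log2 fold change of 2.06. MT-TC (tRNA cysteine, 5761 to 5826) rose from 204 CPM ± 114 to 856 CPM ± 279 (SD, n = 2), a log2 fold change of 2.07 ± 0.33 with an adjusted p of 0.0178. MT-TN (asparagine) rose by 2.06 ± 0.31, and with DESeq2 MT-TC and MT-TN did not pass (adjusted p 0.185 and 0.174). MT-TS2 (serine) rose by 2.58 ± 0.25, MT-TP (proline) by 1.83 ± 0.15 and MT-TW (tryptophan) by 3.38 ± 0.31. These genes are 59 to 75 bases long, so their counts hold short fragments or fragments that reach unannotated bases. Both mitochondrial rRNAs missed the threshold over all genes, with 0 past DESeq2, and passed only adjusted over their list of 2 genes. For MT-RNR2 the groups overlapped, at 3933 and 1217 CPM in unlabelled and 2668 and 12949 CPM in labelled libraries. The 12S rRNA MT-RNR1 (648 to 1601) had a log2 fold change of 1.78 ± 0.55 (edgeR adjusted p 0.303) and the 16S rRNA MT-RNR2 (1671 to 3229) had 1.6 ± 0.63 (adjusted p 0.381). The median of both was 0.34 without labelled replicate 2 and 2.76 without unlabelled replicate 1, so these libraries set its size. Genes annotated on the plus strand had a median log2 fold change of 1.99 and those on the minus strand 2.01. The difference was smaller than the spread of 0.30 (SD) between pairs of libraries. Because the counts were unstranded, these medians cannot separate the RNA made from each strand.

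Among nuclear pseudogene copies of mitochondrial genes, 14 of 43 rose over all genes, 25 were higher and 3 lower adjusted over the list alone, and the median log2 fold change was 1.31. MTCO3P12 on chromosome 1 (634376 to 634922) rose by 2.27 ± 0.15, MTND4P12 on chromosome 5 by 2.27 ± 0.15 and MTND2P28 on chromosome 1 by 2.14 ± 0.15, each with an edgeR adjusted p of 3.11e-05. These copies are near identical to the mitochondrial genes and their reads cannot be assigned with certainty.

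Outside mitochondrial sequences, 14 nuclear genes rose and 3 fell. The rises included both immediate early transcription factors FOS and EGR1 and genes of nuclear RNA-binding proteins. FOS (ENSG00000170345, chromosome 14, 75278826 to 75282230) went from 6.41 CPM ± 1.81 to 19.5 CPM ± 2.12 (SD, n = 2), a log2 fold change of 1.57 ± 0.22 (edgeR adjusted p 0.00722). EGR1 (chromosome 5, 138465479 to 138469303) rose from 75.0 CPM ± 1.32 to 156 CPM ± 21.7, a log2 fold change of 1.06 ± 0.14 (adjusted p 0.00473). HMGN5, a nucleosome-binding protein gene on the X chromosome (81113699 to 81201913), rose from 31.5 CPM ± 0.833 to 82.6 CPM ± 4.27, a log2 fold change of 1.39 ± 0.13 (adjusted p 2.89e-04).

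HNRNPA3 and HNRNPH3, which encode heterogeneous nuclear ribonucleoproteins that bind pre-mRNA, rose by 0.93 ± 0.15 and 0.88 ± 0.14 on the log2 scale. Their exons overlap those of NFE2L2 and RUFY2, in that order, on the opposite strand, so fragments over shared bases stay unassigned. MALAT1, a nuclear-retained long non-coding RNA (chromosome 11, 65497640 to 65508073), rose by 1.01 ± 0.14 (edgeR adjusted p 0.00874). Fragments over exons it shares with TALAM1 on the opposite strand stay unassigned and are missing from its counts. PRR36, which overlaps ENSG00000268120 on the opposite strand, rose by 1.32 ± 0.22 (edgeR adjusted p 0.0296, and 0.0501 with thinning). The unnamed genes ENSG00000290578 (chromosome 1, 146321214 to 146401647) and ENSG00000285646 (chromosome 1, 11907940 to 11914298) rose by 2.37 ± 0.36 and 1.68 ± 0.23, and both overlap another annotated gene. A further 4 rises were DDIT4, TAF15, MRFAP1L1 and GAR1, at 0.77 to 0.85; the last 3 fell outside the rule for named genes and were chosen after their values were seen. Of the nuclear genes named by the rule, HNRNPA3, HNRNPH3, EGR1 and DDIT4 lost the call without labelled replicate 1 and HNRNPA3, HNRNPH3, DDIT4, MALAT1 and ADAMTSL4 lost it without labelled replicate 2, with log2 fold changes of 0.79 to 1.00 in size.

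ADAMTSL4 (chromosome 1, 150549369 to 150560937) fell by 0.97 ± 0.15 on the log2 scale (edgeR adjusted p 0.0117). Its exons overlap ADAMTSL4-AS1, ADAMTSL4-AS2 and MCL1 on the opposite strand, so fragments over shared bases stay unassigned. The ribosomal protein pseudogene RPL39P3, also chosen after its values were seen, had a log2 fold change of -0.96 ± 0.14 (adjusted p 0.0101), and its parent RPL39 had -0.84 (adjusted p 0.0809), so reads shared between them are uncertain. The unnamed gene ENSG00000289136 (chromosome 2, 3650922 to 3652083) stood at 12 CPM and 219 CPM in the unlabelled and at 1.87 CPM and 0.770 CPM in the labelled libraries, so unlabelled replicate 2 set most of its fold. Its edgeR adjusted p of 0.0489 became 0.0520 with the CPM filter, 0.0512 with rRNA genes left out and 0.0520 with the GC and length trend removed.

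**Figure D4:**
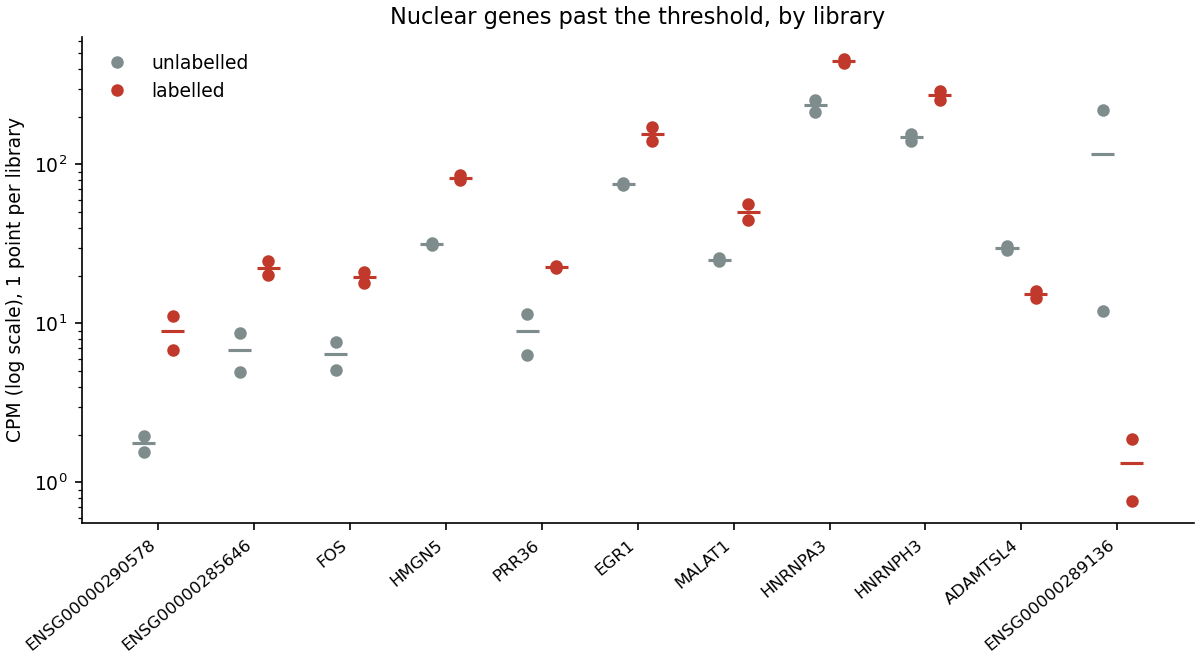
CPM on a log axis for nuclear genes named by the rule, with 1 point per library and a short line at each group mean. The labelled libraries lie above the unlabelled ones for 9 genes and below them for ADAMTSL4 and ENSG00000289136, whose unlabelled points lie at 12 CPM and 219 CPM.

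The gene lists asked whether groups of transcripts moved together relative to all other genes. With camera at its preset correlation, 11 of 22 lists passed an adjusted p under 0.05, and 0 did with an estimated correlation, where 0 lists had an unadjusted p under 0.05 and the adjusted p of these 11 lay between 0.431 and 0.520. Mitochondrial mRNAs (adjusted p 2.20e-21, 0.431 with an estimated correlation), tRNAs (1.50e-24, 0.431) and the pseudogene copies (1.29e-12, 0.431) were higher. The mitochondrial rRNAs did not pass (adjusted p 0.113), but passed with library size alone (5.94e-04) and without labelled replicate 1 (0.00112). fry, which tests whether the genes of a list move one way on balance, passed only the list of fibroblast and endothelium markers, with 3 genes tested.

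Nuclear-encoded respiratory chain subunits, made outside the mitochondria, had a median below 0, opposite in sign to the mitochondrial mRNAs. Of 78 members 13 had a positive log2 fold change, and the median was -0.17 (camera adjusted p 9.78e-05, and an adjusted p of 0.520 with an estimated correlation). No member passed edgeR or DESeq2 over all genes, 26 had an unadjusted p under 0.05, and 9 were lower adjusted over the list alone. COX5B was at -0.58, ATP5F1E at -0.54 and NDUFB7 at -0.49. Cytosolic ribosomal protein mRNAs had a median of -0.26 over 82 members (adjusted p 5.25e-09, and an adjusted p of 0.520 with an estimated correlation), with 0 members past edgeR and 9 past DESeq2 over all genes, 30 at an unadjusted p under 0.05 and 11 lower adjusted over the list alone. RPL39 was at -0.84, RPS29 at -0.77 and RPS21 at -0.74. Without unlabelled replicate 1 both lists missed the threshold, at adjusted p-values of 0.270 and 0.0798, and their medians were -0.05 and -0.12. Without unlabelled replicate 2 the median of the respiratory chain subunits was -0.26.

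The remaining lists of nuclear-encoded mitochondrial genes did not pass camera. The mitochondrial ribosomal proteins had a median of 0.07 over 77 members (adjusted p 0.257) and 1 lower member adjusted over the list alone, with MRPL52 at -0.62, MRPL55 at -0.42 and MRPL9 at 0.76. The matrix enzymes had 0.09 over 37 members (0.0866), led by PDHX at 0.43, MTHFD2 at 0.37 and SOD2 at 0.36. The factors of mitochondrial gene expression had 0.05 over 34 members (0.128), led by TWNK at 0.50, MTPAP at 0.46 and GFM2 at 0.39. In the last 2 of these lists 0 members passed edgeR adjusted over the list alone or DESeq2, and 4 and 3 members had an unadjusted p under 0.05. The mitochondrial ribosomal proteins and the matrix enzymes passed camera as higher without unlabelled replicate 1 (adjusted p 0.00403 and 4.02e-05, medians 0.16 and 0.28) and without labelled replicate 1 (0.0499 and 0.0348).

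Short structured RNAs went in both directions. Small nucleolar RNAs had a median of -0.40 over 76 members (camera adjusted p 9.61e-04, and an adjusted p of 0.520 with an estimated correlation), with 0 members past edgeR and 1 past DESeq2 over all genes, 14 at an unadjusted p under 0.05 and 4 lower adjusted over the list alone. SNORD17 was at -1.15, SCARNA5 at -1.08 and SNORA73B at -0.78. Without unlabelled replicate 2, the shallowest library and the one with most RN7SL and snoRNA fragments (2.84% and 0.620%), this list had a median of -0.12 and an adjusted p of 0.355, and with library size alone its adjusted p was 0.555. The list of abundant small non-coding RNAs had a median of 1.04 over 9 tested members (camera adjusted p 0.0139, and 0.431 with an estimated correlation), with 5 higher and 1 lower adjusted over the list alone. The spliceosomal RNA genes RNU5B-1 and RNU4-2 were at 1.45 and 1.07, with unlabelled means of 2.64 and 5.22 CPM. RMRP, the RNA of RNase MRP, was at -1.10, from 2368 to 1108 CPM. All 21 genes of the list together took 17140 and 28681 CPM of assigned fragments in unlabelled against 10031 and 10700 in labelled libraries. The median therefore does not describe the bulk of these fragments, which fell. That list had an adjusted p of 0.0622 without unlabelled replicate 1 and 0.0501 with all libraries thinned to the lowest total. Nuclear long non-coding RNAs did not pass (median -0.25 over 13 members, adjusted p 0.257, 1 member higher and 4 lower adjusted over the list alone), with NEAT1 at -0.82 and KCNQ1OT1 at -0.54 beside MALAT1. They passed as lower without unlabelled replicate 1 (median -0.55, adjusted p 0.0191).

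The lists of immediate early, integrated stress, p53 target and heat shock genes were higher in labelled libraries by camera at its preset correlation. Immediate early and short-lived mRNAs had a median log2 fold change of 0.39 over 33 members (camera adjusted p 2.09e-10, and an adjusted p of 0.431 with an estimated correlation). FOS and EGR1 passed over all genes and 10 members adjusted over the list alone. JUN was at 0.70. Integrated stress response genes had a median of 0.33 over 23 members (adjusted p 7.96e-08, and an adjusted p of 0.431 with an estimated correlation), with DDIT4 past over all genes, 5 adjusted over the list alone, STC2 at 0.65 and CHAC1 at 0.70. p53 target genes had 0.20 over 20 members (adjusted p 6.00e-04, and an adjusted p of 0.450 with an estimated correlation), with 1 member past adjusted over the list alone, GADD45A at 0.59, PLK3 at 0.83 and SESN2 at 0.33.

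Heat shock genes had a median of 0.22 over 18 members (camera adjusted p 0.00145, and an adjusted p of 0.520 with an estimated correlation), with 1 member past adjusted over the list alone. HSPA1A was at 1.6, BAG3 at 0.48 and DNAJB4 at 0.37, while HSPA1B, a near-identical copy of HSPA1A named here after its value was seen, was at 0.14, so the split of reads between these copies is uncertain. Without unlabelled replicate 2 the heat shock list had a median of 0.08 and an adjusted p of 0.151, and without unlabelled replicate 1 its median was 0.37. With library size alone the medians of the integrated stress, heat shock and p53 lists were -0.02, -0.13 and -0.15, against a median of all genes of -0.37.

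No shift was detected by camera in the other lists. Histones had a median of -0.05 over 49 members (adjusted p 0.542), with H2BC26 at -0.39, H2AC16 at -0.36 and H2AC4 at 0.41. Endoplasmic reticulum chaperones and translocation factors had 0.05 over 34 members (0.262), with 1 lower adjusted over the list alone, HSPA5 at 0.60, SSR4 at -0.55 and CRELD2 at -0.30. Oxidative stress genes had a median of 0.05 and a mean of -0.03 over 25 members (0.820), with FTH1 at -0.59 and KEAP1 at 0.38. Cytosolic housekeeping mRNAs had -0.04 over 23 members (0.685), with TMSB10 at -0.36, TPI1 at -0.28 and LDHB at -0.23. Without unlabelled replicate 1 the histone, housekeeping and endoplasmic reticulum lists were higher, with medians of 0.17, 0.29 and 0.27 and adjusted p-values of 0.00759, 8.09e-04 and 3.52e-04. Without unlabelled replicate 2 the histone and housekeeping lists were lower, with medians of -0.19 and -0.29 and adjusted p-values of 3.63e-05 and 2.97e-06. In the histone, oxidative stress and housekeeping lists 0 members passed edgeR adjusted over the list alone or DESeq2, and 4, 4 and 1 had an unadjusted p under 0.05.

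Markers of other cells were near the detection limit. Of 16 blood cell markers 3 were tested (camera adjusted p 0.753), with CSF1R and CD14 below 4 CPM on average in both groups. Of 16 fibroblast and endothelium markers 3 were tested (camera adjusted p 0.262, fry adjusted p 0.00390), with COL1A1 at 0.35, ACTA2 at -0.96 and THY1 at -0.54 on the log2 scale. All 16 genes of each list together took 19.3, 24.1, 15.2 and 12.7 CPM of assigned fragments for blood cells and 31.6, 26.0, 24.2 and 22.5 for fibroblasts and endothelium, in unlabelled and then labelled libraries.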

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

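The fit with the GC and length trend removed and the settings for the strand comparison were chosen after seeing the data; the other alternatives were fixed before. The mitochondrial share kept its direction under every alternative tried, with differences of 18.8 percentage points without rRNA genes, 19.4 over protein-coding genes and 17.3 to 21.2 with single libraries left out. All 54 genes past the threshold kept their direction under every refit. Their number was 2744 with library size alone (69 higher, 2675 lower), 302 with no filter (183 higher, 119 lower), 82 with DESeq2 (63 higher, 19 lower) and 31 at an adjusted p under 0.01. With single libraries left out it ranged from 58 to 3985, because a fit with 1 library in a group takes its spread from the other group, and the lone library is assumed to vary alike. It was 57, 57, 53, 56, 54 and 68 with DESeq2 size factors, nuclear genes only, the CPM filter, thinning, rRNA genes left out and the GC and length trend removed, and 45 with a change of at least 2-fold. The median of the mitochondrial mRNAs was 1.6 with library size alone, by the shift of all genes to -0.37, and 1.74 to 2.08 with single libraries left out. The area under the ROC curve was 0.914 with no filter, where 39689 genes were tested, and 0.975 to 0.998 with single libraries left out. The strand difference stayed within its spread, at -0.28 to 0.25.

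The number of gene lists past the threshold was 11 with most alternatives, 10 with thinning, 11 to 14 with single libraries left out, 0 with an estimated correlation and 1 with fry. With library size alone 10 of the 11 lists still passed, all but the small nucleolar RNAs (adjusted p 0.555), and thinning ended the call of the small non-coding RNAs (0.0501). The histone and housekeeping lists turned from lower to higher without unlabelled replicate 1 (adjusted p 0.00759 and 8.09e-04), and their adjusted p ranged from 3.63e-05 to 0.837 and from 2.97e-06 to 0.933 with single libraries left out; the cause was not tested. Of 85 named genes, the 25 past the threshold kept their sign throughout, and 6 of the others changed sign under some setting. With DESeq2 2 named genes lost the call and 14 gained it, and with library size alone none lost it and 32 gained it.

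The replicate numbers are shared by the groups but are not stated to mark a shared batch. With the replicate number as a block 236 genes passed (140 higher, 96 lower). Same-numbered libraries had deviations with a correlation of -0.07 across 18973 genes. The mitochondrial share differed by 17.95 and 20.48 percentage points within replicate numbers 1 and 2, and 11 lists passed camera with the replicate block. The fibroblast and endothelium list, past fry at an adjusted p of 0.00390, had 0.199 with the block. Thinned to the 5771795 fragments of the shallowest library, 20 tRNAs were tested as before, but 55 in place of 76 small nucleolar RNAs and 32 in place of 43 pseudogene copies.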

Other observations

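The gene families, the comparisons of count ratios and the fit with the GC and length trend removed were chosen after the result was seen, and so was the use made below of alternatives fixed before. Gene families were chosen by symbol, 15 in all. Those that did not pass camera included the H/ACA and C/D snoRNP proteins and the FET proteins, the families of GAR1 and TAF15. Without these genes their medians were 0.07 and 0.03 (camera adjusted p 0.258 and 0.820). Families not described here did not pass camera either. The family of hnRNP proteins was chosen because HNRNPA3 and HNRNPH3 had passed the edgeR threshold. Of its 19 other members 16 had a positive log2 fold change, with a median of 0.25 (camera adjusted p 1.94e-04, and an adjusted p of 0.613 with an estimated correlation), and over all 21 members the median was 0.27. HNRNPAB was at 0.50 and HNRNPA1 at 0.65, neither past the threshold. SR splicing factor genes had a median of 0.18 over 12 members (adjusted p 0.0241, and 0.544 with an estimated correlation). All 10 TCEAL and BEX genes had positive values, with a median of 0.34 and TCEAL4 at 0.64 (camera adjusted p 3.10e-04, and 0.544 with an estimated correlation). With library size alone the median of all genes was -0.37, so the medians of the hnRNP, SR and TCEAL and BEX genes turned to -0.09, -0.18 and -0.02. Relative to all genes they were 0.28, 0.19 and 0.35, and the SR list no longer passed (adjusted p 0.487). That list also missed the threshold without unlabelled replicate 2 (0.0828) and without labelled replicate 2 (0.126).

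Ribosomal protein pseudogenes went the other way, with a median of -0.41 over 210 members, 40 of them positive (camera adjusted p 4.18e-10, and 0.544 with an estimated correlation). They share reads with the ribosomal protein genes, which had a median of -0.26. By biotype, protein-coding nuclear genes had a median log2 fold change of 0.02, processed pseudogenes -0.25, lincRNAs -0.15, snoRNAs -0.32 and miRNA genes -0.47. Their median lengths were 5364, 730, 2573.5, 132 and 85 bases, in that order, so RNA class and gene length cannot be told apart here. The GC and length trend was not removed in the tests of lists and families. Small nuclear RNAs, pseudogenes included, had 0.33 over 58 genes, at a median length of 116 bases. The 45 genes with symbols of U small nuclear RNAs were 36 pseudogenes by symbol, with a median of -0.17 and 15 positive values, and 9 others, all positive, at 0.43 to 1.47. The median of the pseudogenes turned to 0.28 without unlabelled replicate 2, 0.14 without labelled replicate 2 and 0.20 over the 15 tested with thinning. Of the 9, 0 passed edgeR or DESeq2 over all genes, 8 had an unadjusted p under 0.05, and all 9 stayed positive with each other scaling and filter and with each library left out. Their unlabelled means were low, from 1.52 CPM for RNU1-2 to 7.19 CPM for RNU5F-1, and these refits reuse the same few counts. Multi-mapped reads were not counted, so the values need not describe the spliceosomal RNAs as a whole. All 45 as a list had an adjusted p of 0.0411, 0.539 without unlabelled replicate 1, and 0.660 with an estimated correlation.

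MT-ATP8 and MT-ND3 had a mean log2 fold change of 0.57, against a median of 2.01 for the other 11 mitochondrial mRNAs. MT-ATP8 was 3.35% and 5.59% of mitochondrial mRNA counts in unlabelled and 1.44% and 1.58% in labelled libraries. The gap was -0.99 without unlabelled replicate 2 and -1.38 with the GC and length trend of nuclear genes removed, against -1.44 before, so neither that library nor that trend alone made it. For MT-ATP8 a loss by transcript length is argued against, because MT-ATP6 lies on the same mRNA, yet the ratio of MT-ATP8 to MT-ATP6 counts was 0.408 and 0.696 in unlabelled and 0.198 and 0.226 in labelled libraries, a log2 change of -1.82 to -0.85 over the 4 pairs of libraries. The shortest mitochondrial mRNA genes, MT-ATP8 (207 bases), MT-ND4L (297) and MT-ND3 (346), also had the lowest values, with MT-ND4L at 1.53. Nuclear genes of up to 400 bases took 2.96% of unlabelled and 1.46% of labelled fragments, though the share of all nuclear genes fell too. RN7SL genes alone took 2.22% and 1.04%, so that fall was mostly theirs and does not describe short genes in general. For MT-ATP8 the same ratio also argues against a difference in labelling of the mRNA as a whole, which would move MT-ATP6 alike. Fragments left unassigned because they touch both MT-ATP8 and MT-ATP6 stay open. For MT-ND3 a length effect beyond the nuclear trend and a real difference in labelling stay open. The explanations left open were not tested.

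The mitochondrial rRNAs spread widely within both groups, at 8.32 and 2.28 counts per 100 mitochondrial mRNA counts in unlabelled and 1.76 and 6.26 in labelled libraries. Uneven rRNA removal is a candidate explanation, since all 4 libraries had the same order by this ratio and by multi-mapped records per assigned nuclear fragment (3.04, 1.38, 0.885 and 1.88), although those records were not identified as rRNA. Whether mitochondrial rRNAs were enriched less than the mRNAs cannot be told apart from this spread, because the groups overlap and the log2 ratio of their means was -0.40.

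Of the 17 nuclear genes past the threshold outside the pseudogenes, 16 stayed past it in the same direction with the GC and length trend removed. GC content and gene length are argued against for all but ENSG00000290578 and ENSG00000289136. GC content was not known for these genes, so no trend was removed from them and that fit cannot decide. ENSG00000289136 went from -6.47 ± 1.18 (SE) to -6.47 ± 1.21 on the log2 scale. Its edgeR adjusted p went from 0.0489 to 0.0520, by a wider error and not a smaller fold. A response of short-lived mRNAs to the D-amino acid incubation may explain FOS and EGR1. Their list had a camera adjusted p of 0.431 with an estimated correlation. The mitochondrial mRNA list had 0.431 as well, and 0 of 22 lists passed that test, so it cannot decide here. RNA before enrichment was not analysed here, so a change in the cells cannot be told apart from a change in what was captured.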
